A study of Mus musculus with 6 samples.

How the data were processed

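The data are total RNA sequencing libraries, 6 in all and 3 per group, with the groups and replicate numbers taken from the sample titles. The deposited table holds raw read counts per gene, not normalized, for all 6 libraries, with a gene symbol, an Entrez number and annotation terms for each gene. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V10 kit. fastp, HISAT2 and HTSeq are named in the submitters' processing notes without versions or roles. The genome build, the gene annotation and whether counting used strand are not given in the sources used here, and neither is the time between reoxygenation and harvest.

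The organism in the labels is mouse, while the table's symbols, Entrez numbers and KEGG and Reactome terms are human. Only mouse reference tables were at hand, so they served to check the Entrez numbers, and no coordinates are given. The gene lists had been fixed with mouse symbols before the data were examined. They were carried over to human symbols by name, with a table of the pairs whose names differ, and mouse genes without a human counterpart were left out. Members without a row are called not listed. CPM denotes reads of a gene per 1000000 reads of the TMM-scaled library total.

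All 20499 listed genes have at least 1 read, and 0 rows name no gene. Genes were kept for testing by the filterByExpr function of edgeR with its default minimum count of 10, which left 13489, of which 12022 are protein-coding and 1467 non-coding by the table's own types. Counts were scaled with TMM factors, dispersions were estimated, and the 2 groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with group as the sole term and 2-sided p-values adjusted by Benjamini-Hochberg over all tested genes. A gene counts as changed at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are given as mean ± SD over 3 libraries. The common biological coefficient of variation was 4.82% and the median standard error of a log2 fold change 0.0711, so that changes of well under 1.25-fold could pass for well-expressed genes.

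Gene lists were tested with camera (limma 3.58.1) against all other tested genes, with the preset correlation of 0.01 between genes, over the 35 lists with at least 5 tested members, and again with the correlation estimated from the data. Members were also counted as changed with adjustment over the list alone. The genes named in the text follow a rule set before the data were examined. It takes RNF11 and HINT1, up to 6 changed members of the PI3K, AKT and mTOR list, and the 8 highest and 8 lowest fold changes among changed genes with a mean of at least 5 CPM in the higher group and no overlap between groups. Its rankings pass over symbols beginning LOC, or beginning AC, AL or Gm plus digits, or ending Rik. The rule also adds up to 4 members with the smallest p of each list that passed camera or had at least 3 changed members. Genes outside the rule are said to have been chosen after their values were seen, except those in the paragraph on cell identity, which are named for their levels.

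The fit was tested on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed by known amounts. Of the changed genes among the 13311 that passed the filter, it recovered 24 of 49 changed by 0.25 on the log2 scale, 32 of 50 at 0.5, 43 of 49 at 1 and 49 of 49 at 2, with 7 false calls (4.52% of calls) and 0 of 34 lists called. Simulated genes are independent, unlike real ones, so this does not test the lists' correlation. The simulated changes were balanced between higher and lower and far fewer than the 4336 called in the real libraries. The simulation therefore does not test the scaling under a broad shift, and its share of false calls may not carry over. Replicates of a group were compared by a chi-square statistic per gene over genes with at least 20 reads summed over a pair. It was 3.79 to 5.85 within groups and 21.4 to 23.8 between groups, so no pair of libraries was a duplicate within sampling noise. The first principal component of log CPM held 40.7% of the variance and separated the arms. The second held 16.6% and set shRNF11 replicate 1 (-26.4) apart from replicates 2 (13.6) and 3 (11.5) of its arm.

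Alternatives set before the data were examined were DESeq2-style and upper-quartile factors, library totals alone, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Added after seeing the data were protein-coding genes only, a minimum fold of 2, and the comparison of list medians with 10000 random lists of the same size matched on mean expression, in which each member was replaced by a tested gene among the nearest in expression. KEGG terms came from the table itself, with 313 terms of 10 to 300 tested genes. Genes and samples beyond those listed were not analysed here.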

Results

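RNA was profiled by sequencing in 6 libraries of cells that the labels describe as AML12, an immortalized mouse hepatocyte line. Per the labels, the cells of all 6 libraries had been through hypoxia and reoxygenation, a culture model of liver ischemia and reperfusion. The protocol was 6 h at 1% oxygen in medium free of glucose and serum, followed by complete medium in normal air. That complete medium held 10% serum and dexamethasone, a synthetic glucocorticoid, at 40 ng/mL. In 3 libraries (shRNF11) the ubiquitin ligase gene RNF11 had been knocked down with a lentivirus, and 3 libraries (shControl) carried the control virus. Library depth ranged from 37485850 to 39045440 counts over 20499 listed genes. No library without hypoxia was analysed here, so each value below compares the 2 arms after reoxygenation. The labels do not say that the replicates came from separate cultures, and the p-values then measure only the spread between these libraries, which may be technical.

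The identity of the cells bears on every value. The count table names human genes, although the labels give mouse: none (0) of its 20499 Entrez numbers is among the 49997 genes of the mouse RefSeq table, 6391 of its genes carry human KEGG terms and 0 carry mouse ones. Genes of secreted hepatocyte proteins had almost no reads, with 1 read of APOA1, 6 of APOB and 42 of FGG in all 6 libraries together. The epithelial keratin KRT7 reached 2315 ± 41.6 CPM (reads per library scaled to a common total; SD, n = 3) in shControl, the intermediate filament gene VIM 1241 ± 8.14 CPM, and CPS1, the first enzyme of the urea cycle, 1028 ± 22.1 CPM. Of the 36 hepatocyte markers fixed in advance, 23 were listed and 8 had enough reads to be tested. Gene symbols are given as the table prints them, and cells are called the shControl and shRNF11 cells throughout.

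RNF11 itself (Entrez 26994) was lower in every shRNF11 library. The 3 shControl libraries held 2050, 1926 and 1930 reads of it and the 3 shRNF11 libraries 573, 565 and 599. Mean expression went from 51.0 ± 1.69 CPM to 15.3 ± 0.475 CPM (SD, n = 3 each), which was 3.32-fold lower (log2 fold change -1.73, SE 0.0633, adjusted p = 3.48e-28, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The group labels thus matched the targeted transcript in all 6 libraries.

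The title of the series links RNF11 to breakdown of the protein HINT1 and to PI3K/AKT signalling, and the transcripts of these genes were read next. HINT1 (Entrez 3094), which encodes a small nucleotide-binding hydrolase, was 1.13-fold higher in shRNF11 cells, at 244.2 ± 8.15 CPM against 215.7 ± 0.603 CPM (SD, n = 3 each; log2 fold change 0.18, SE 0.0309, edgeR adjusted p = 7.03e-06). The 3 shRNF11 libraries all lay above the 3 shControl libraries. HINT1 lay in the fifth of tested genes with the highest expression, where the median log2 fold change was 0.0647 and 1154 of 2698 genes were higher. Higher expression was thus common among genes as abundant as HINT1, although the 0.18 of HINT1 lay above that median. The difference in HINT1 did not pass a test against a 1.5-fold change. Protein amounts and AKT phosphorylation were not analysed here.

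Genes of the PI3K, AKT and mTOR pathway moved in both directions. Of the 28 components fixed in advance, all tested, 5 were higher, 7 were lower and 16 did not pass; adjusted over the list alone the counts were also 5 and 7. IRS2, an adaptor of the insulin receptor, was 1.39-fold higher at 95.1 ± 3.17 CPM against 68.6 ± 1.95 CPM (SD, n = 3 each), and PIK3CD, a catalytic subunit of PI3K, was 1.35-fold higher. RICTOR, the defining subunit of mTOR complex 2, was 1.18-fold lower, RPTOR, its counterpart in complex 1, 1.15-fold lower, and the receptor IGF1R and the lipid phosphatase INPPL1 were each 1.11-fold lower. The call on RPTOR, whose arms overlapped, was lost in DESeq2 (adjusted p = 0.0989). The median log2 fold change of the list was -0.05, and the list did not stand apart from the other tested genes (camera adjusted p = 0.593). FOXO target genes, which AKT holds down through FOXO factors, also went both ways: 5 of 20 tested were higher and 8 lower (camera adjusted p = 0.742), with GADD45A 1.47-fold higher and PPARGC1A, a coactivator of mitochondrial genes, 1.85-fold lower. Adjusted over the list alone, 6 were higher and 8 lower. Ligases and ubiquitin-editing proteins known to bind RNF11 or A20 showed 3 of 16 higher, 3 lower and 10 that did not pass (camera adjusted p = 0.793). NEDD4 was 1.36-fold higher among them and TNFAIP3, which encodes A20, 1.25-fold lower.

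**Figure D1:**
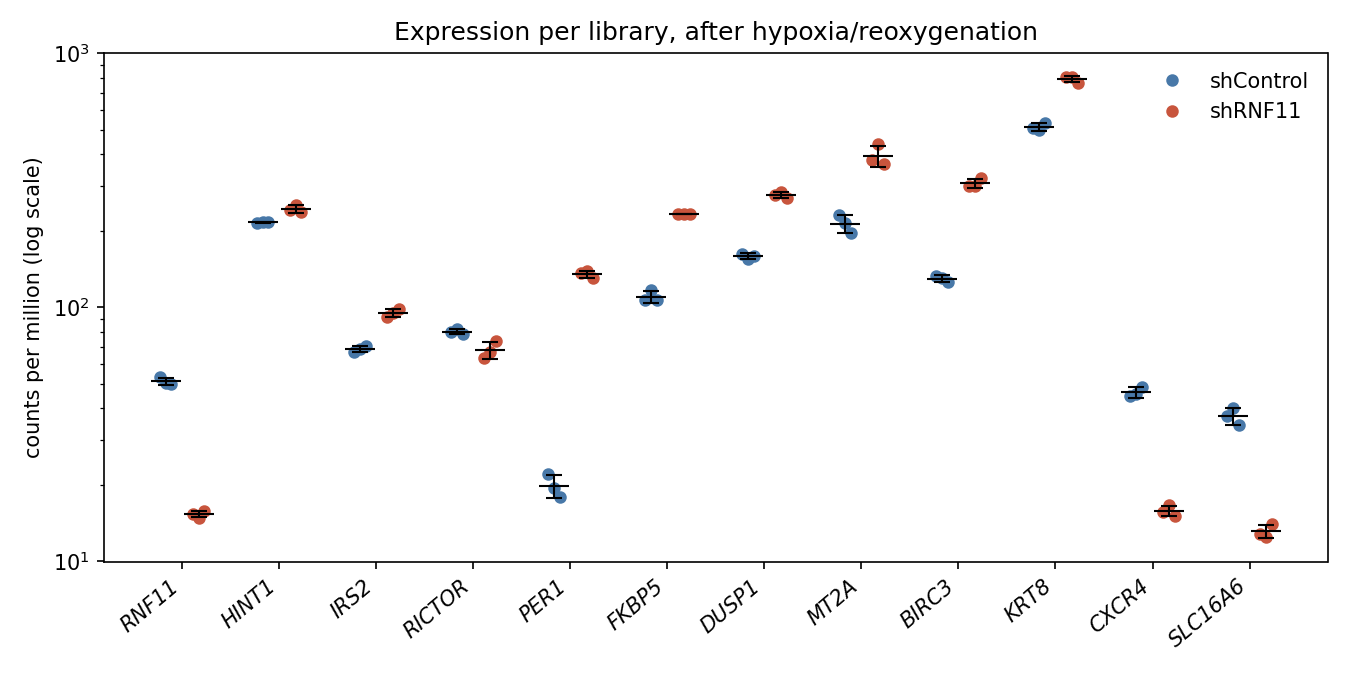
Expression of 12 genes in each library (vertical axis, CPM on a log scale). Points are the 3 shControl and 3 shRNF11 libraries, the long bar is the mean and the error bars are the SD; RNF11 fell from 51.0 to 15.3 CPM and PER1 rose from 19.8 to 134.8 CPM, with no overlap between arms for either gene.

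Across the transcriptome the arms differed at many genes, mostly by little. Of 13489 genes tested, 4336 (32.1%) passed the threshold of an adjusted p of 0.05, 2348 higher and 1988 lower in shRNF11 cells. The median change among them was 1.17-fold, 2987 changed by under 1.25-fold, and 215 changed at least 2-fold, 92 of them higher and 123 lower. The arms' libraries did not overlap for 42.8% of the tested genes, where chance gives 10%. The division into higher and lower genes rested on the scaling: 54.2% of the changed genes were higher with TMM factors, whose group means were 1.02 in shControl and 0.978 in shRNF11, and 29.1% were higher when libraries were scaled by their totals alone (1335 higher, 3255 lower). Fold changes also followed abundance, with a median log2 fold change of -0.157 in the fifth of tested genes with the lowest expression and 0.0647 in the fifth with the highest.

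**Figure D2:**
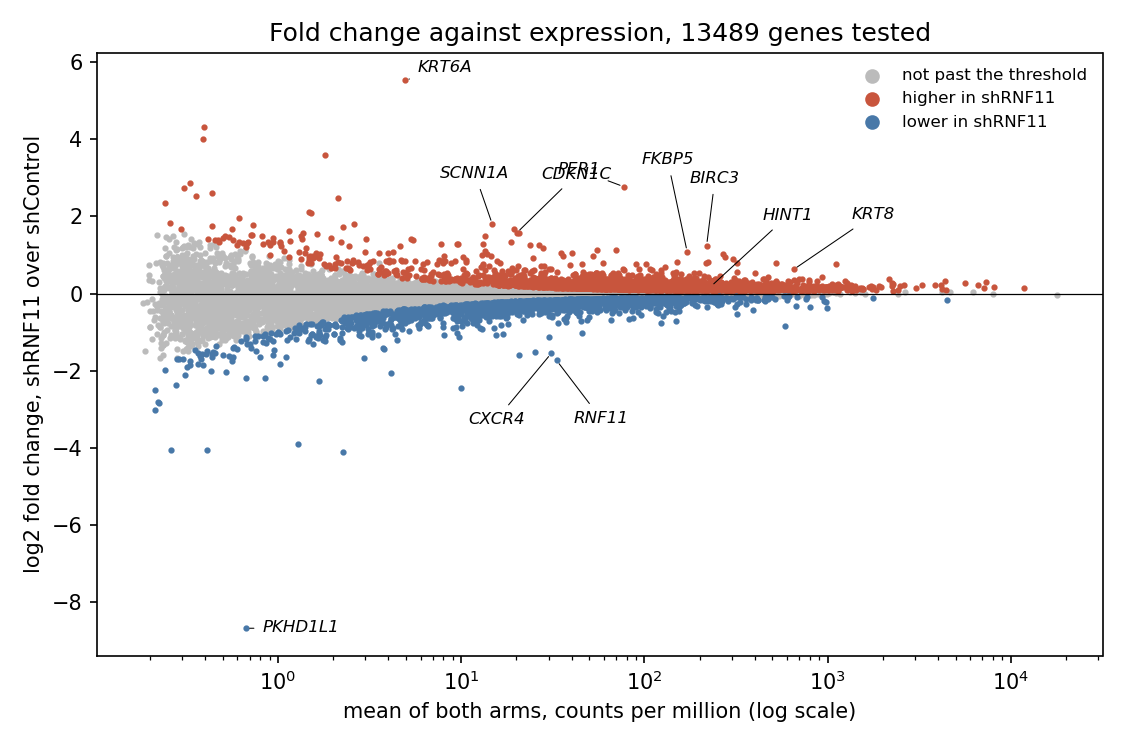
Log2 fold change of each tested gene (vertical axis, shRNF11 over shControl) against its mean expression in both arms (horizontal axis, CPM on a log scale). Red and blue points are the 2348 higher and 1988 lower genes and grey points did not pass; red points gather on the right, where expression is high, and KRT6A, PER1 and RNF11 lie far from 0.

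The genes that rose most in shRNF11 cells included epithelial, glucocorticoid-responsive and metal-binding genes. KRT6A (Entrez 3853), a keratin of stressed and wounded epithelia, had 2, 5 and 17 reads in the shControl libraries and 364, 392 and 338 in the shRNF11 libraries, or 0.207 ± 0.205 CPM against 9.66 ± 0.700 CPM (log2 fold change 5.52, SE 0.264). With so few reads in shControl the size of this change is uncertain: leaving out 1 library at a time gave log2 fold changes of KRT6A from 5.07 to 6.68, the highest without shControl replicate 3. Its near-identical copies KRT6B and KRT6C make the assignment of those reads uncertain. PER1, a core clock gene that glucocorticoids also induce, was 6.80-fold higher, at 134.8 ± 4.46 CPM against 19.8 ± 2.13 CPM. SCNN1A, a subunit of the epithelial sodium channel, was 3.48-fold higher, TENT5B, a poly(A) polymerase gene, 3.19-fold, the cell cycle inhibitor CDKN1C 2.97-fold, the metallothionein MT1E 2.96-fold, the lipase inhibitor ANGPTL4 2.80-fold and the basement membrane collagen COL18A1 2.67-fold. The edgeR adjusted p of these 8 genes was at most 1.58e-10. Metallothionein genes resemble one another, and reads may be split among them.

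The ranked genes had a mean of at least 5 CPM in the higher arm, no overlap between arms and a symbol kept by rule. Among those that changed, RNF11 showed the steepest fall. After it came CXCR4, a chemokine receptor, which was 2.93-fold lower, at 15.8 ± 0.763 CPM against 46.2 ± 2.13 CPM (SD, n = 3 each). SLC16A6, a transporter of the monocarboxylate family, was 2.85-fold lower, the nuclear receptor NR4A2 2.67-fold, the neuropeptide receptor VIPR2 2.30-fold and SLFN5, an interferon-responsive gene, 2.19-fold. The antisense genes CACTIN-AS1 and BCAN-AS1 were 2.70-fold and 2.20-fold lower, and because the sources used here do not say whether counting used strand, their reads cannot be told from those of the genes opposite. The edgeR adjusted p of these 8 genes was at most 9.67e-08.

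Glucocorticoid target genes formed the group with the largest median shift among the lists tested. All 10 tested members changed, 9 higher and 1 lower, also when adjusted over the list alone, with a median log2 fold change of 0.86 (camera adjusted p = 2.32e-50; adjusted p = 0.0203 with an estimated correlation). Besides PER1, CDKN1C and ANGPTL4, FKBP5, a co-chaperone of the glucocorticoid receptor, was 2.11-fold higher at 232.2 ± 0.348 CPM against 110.1 ± 6.11 CPM, the phosphatase gene DUSP1 1.74-fold higher and MT2A 1.85-fold higher. The 1 member that was lower, singled out after its values were seen, was SGK1, a kinase of sodium transport, at 97.2 ± 2.53 CPM against 135.6 ± 4.27 CPM (log2 fold change -0.48). Dexamethasone was part of the complete medium, per the labels, and the labels give no difference in it between the arms.

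Proteasome subunit genes rose together by small amounts. Of 31 tested, 27 were higher and 0 lower (28 and 0 adjusted over the list alone), and the median log2 fold change was 0.20 (camera adjusted p = 4.52e-12; adjusted p = 0.0203 with an estimated correlation). PSMA7 was 1.22-fold, PSMB3 1.23-fold, PSMB6 1.22-fold and PSMD3 1.17-fold higher. These were the other list, beside the glucocorticoid targets, that passed with an estimated correlation, out of 35 lists tested and 14 past the threshold with the preset correlation.

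Mitotic genes, TGF-beta targets and matrix genes were also higher. Of 30 G2/M genes, 24 were higher and 0 lower, before and after adjustment over the list alone (median log2 fold change 0.21, camera adjusted p = 3.86e-17; adjusted p = 0.0806 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, was 1.45-fold higher, the mitotic kinase gene PLK1 1.43-fold and the cyclin gene CCNB1 1.36-fold. Of 23 TGF-beta and SMAD targets, 13 were higher and 3 lower, alone or over all genes (median 0.25, camera adjusted p = 4.97e-09; adjusted p = 0.0518 with an estimated correlation): the matrix protein gene TGFBI was 1.72-fold higher at 663.3 ± 13.7 CPM against 385.4 ± 14.1 CPM, the transcription factor gene SNAI2 2.07-fold, ID1 1.69-fold and THBS1 1.26-fold. Of 31 matrix and adhesion genes, 19 were higher and 4 lower (20 and 4 adjusted over the list alone; median 0.23, camera adjusted p = 1.41e-05; adjusted p = 0.0518 with an estimated correlation), with the laminin chains LAMB3 2.07-fold, LAMC1 1.26-fold and LAMB1 1.26-fold higher and the integrin ITGA5 1.44-fold higher. The TGF-beta and matrix lists share members such as COL4A1 and FN1.

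**Figure D3:**
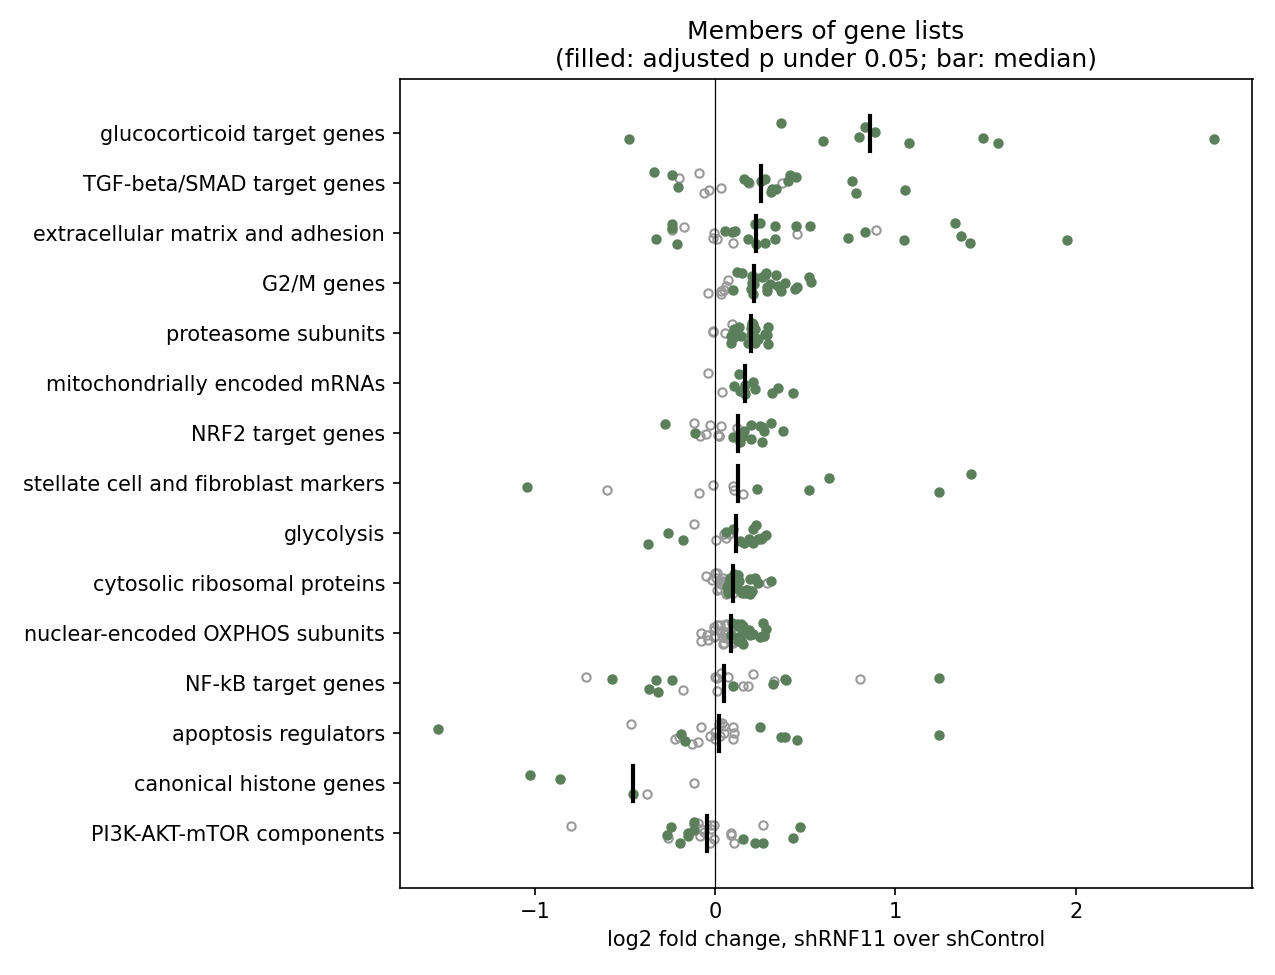
Log2 fold change (horizontal axis, shRNF11 over shControl) of each tested member of the 14 lists past the camera threshold and of the PI3K, AKT and mTOR list. Filled points passed an adjusted p of 0.05, open points did not, and the black bar is the median; the glucocorticoid targets have the highest median, 0.86, and the PI3K, AKT and mTOR members lie on both sides of 0.

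In other divisions of the 6 libraries into groups of 3, camera with the preset correlation passed up to 10 lists, so a pass at that setting also arose between groups of mixed arms. Those groups held unequal numbers of shControl and shRNF11 libraries, so part of the arm difference remained between them. The passes there thus do not measure how often a list passes without any difference. Because fold changes followed abundance, each list's median was also set against 10000 random lists matched on mean expression, a comparison chosen after seeing the data. Each member was drawn separately, so the comparison ignores correlation between the genes of a list, and its p-values can be too small. The 5 lists just described passed the comparison, each with an adjusted p of 0.00140, the smallest these draws gave. Among these 5, only the glucocorticoid and proteasome lists also passed camera with an estimated correlation. A lost pass there need not mean strong correlation: the estimate for the matrix and adhesion list was -0.0217, below the preset 0.01. The other 9 lists past the camera threshold did not pass the comparison. Of those 9, cytosolic ribosomal protein genes had 32 of 52 members higher and 0 lower (35 and 0 adjusted over the list alone; camera adjusted p = 3.22e-08; adjusted p = 0.187 with an estimated correlation), yet their median log2 fold change of 0.1002 lay just under the 0.1038 of the matched lists (adjusted p = 0.821). Reads of these genes can also fall on their many pseudogenes. Among mitochondrially encoded mRNAs 11 of 13 were higher and 0 lower (12 and 1 alone), with ATP6 1.24-fold and CYTB 1.17-fold higher (adjusted p = 0.225 with an estimated correlation, 0.559 against matched lists). Of 44 nuclear-encoded subunits of oxidative phosphorylation, 19 were higher and 0 lower (22 and 0 alone), with COX7C 1.22-fold higher (0.248 with an estimated correlation and 0.0738 against matched lists, both adjusted p). Glycolytic genes included 12 of 20 higher and 3 lower, alone or over all genes, with PKM 1.22-fold, GAPDH 1.20-fold and LDHA 1.19-fold higher (adjusted p = 0.225 with an estimated correlation, 0.388 against matched lists). Of 24 NRF2 targets, 12 were higher and 2 lower (13 and 2 alone), with the peroxiredoxin gene PRDX1 1.30-fold higher (adjusted p = 0.187 with an estimated correlation, 0.0640 against matched lists).

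Genes of cell survival and inflammation changed member by member. Of all tested genes 32.1% changed, so counts near that share do not set a list apart. Near it were the apoptosis (8 of 25 changed), interferon (8 of 23) and p53 (8 of 23) lists. The NF-kB (10 of 22) and immediate early (11 of 21) lists lay above it. BIRC3, an inhibitor of apoptosis and an NF-kB target, was 2.37-fold higher in shRNF11 cells, at 307.2 ± 12.7 CPM against 129.7 ± 3.71 CPM (SD, n = 3 each; edgeR adjusted p = 5.97e-34). Of 25 apoptosis regulators, 5 were higher and 3 lower, alone or over all genes, and the higher ones named by the rule, BIRC3, BIRC5, BIRC2 and BCL2L1, all encode inhibitors of cell death (camera adjusted p = 0.0120; adjusted p = 0.225 with an estimated correlation, 0.821 against matched lists). Of 22 NF-kB targets, 5 were higher and 5 lower, alone or over all genes, with NFKBIA 1.31-fold and SOD2 1.31-fold higher and TNFAIP3 lower (camera adjusted p = 0.0344; adjusted p = 0.187 with an estimated correlation, 0.320 against matched lists). The medians of the apoptosis and NF-kB lists were 0.0186 and 0.0511 on the log2 scale. Interferon-stimulated genes gave 3 of 23 higher and 5 lower (camera adjusted p = 0.699), p53 targets 5 and 3 of 23 (0.801) with CDKN1A 1.52-fold lower, and immediate early genes 6 and 5 of 21 (0.695) with KLF6 1.56-fold higher and IER3 1.58-fold lower. Adjusted over each list alone, these counts were the same except for 6 lower immediate early genes.

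The lists of hypoxia and stress responses, and the others in this paragraph except the histone genes, each included higher and lower members. Of 25 HIF targets, 9 were higher and 7 lower (10 and 7 adjusted over the list alone; camera adjusted p = 0.572): DDIT4, an inhibitor of mTOR complex 1, was 1.32-fold higher and the glucose transporter gene SLC2A1 1.30-fold lower. The integrated stress response had 6 of 25 higher and 9 lower (6 and 11 alone; camera adjusted p = 0.212), chaperones of the endoplasmic reticulum 9 and 2 of 20 (the same alone; 0.131), heat shock proteins 7 and 4 of 16 (the same alone; 0.695) and ferroptosis regulators 4 and 6 of 19 (the same alone; 0.226). Autophagy and lysosome genes had 2 of 26 higher and 7 lower (the same alone; 0.226), and YAP/TEAD targets 8 and 3 of 16 (8 and 4 alone; 0.141). S-phase genes had 5 of 30 higher and 12 lower (5 and 13 alone; 0.299), and their median log2 fold change of -0.0407 lay below that of the matched lists, 0.0555 (adjusted p = 0.00583). Of 5 tested canonical histone genes, 0 were higher and 3 lower, alone or over all genes, H2AC6 by 2.04-fold, H2BC21 by 1.82-fold and H1-2 by 1.37-fold (camera adjusted p = 0.000857; adjusted p = 0.114 with an estimated correlation, 0.118 against matched lists). Histone genes of one cluster are close copies, so single assignments are uncertain.

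Lipid and drug metabolism genes also moved singly. Fatty acid oxidation genes and PPAR-alpha targets had 8 of 20 higher and 2 lower (8 and 3 alone; camera adjusted p = 0.0746), with CPT1A, the gate of mitochondrial fatty acid import, 1.30-fold higher and PDK4 1.79-fold higher. Fatty acid synthesis genes had 5 of 18 higher and 7 lower (5 and 8 alone; 0.305), with the desaturase gene SCD 1.29-fold lower. Cholesterol synthesis genes had 7 of 24 higher and 5 lower (the same alone; 0.859). Among 9 xenobiotic metabolism genes 1 was higher and 4 lower (the same alone; 0.742), with a median log2 fold change of -0.221. The transporter gene ABCC2 was 1.45-fold higher, while its relative ABCC3 was 1.17-fold lower, the drug exporter gene ABCB1 1.29-fold lower and the oxidase gene CYP1A1 2.74-fold lower. The calls on ABCB1 and CYP1A1 were lost when certain single libraries were left out, and that on CYP1A1, whose log2 fold change then ranged from -2.46 to -0.972, also in DESeq2.

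Markers of cell types were few. Among the 8 tested hepatocyte markers 3 were higher and 1 lower, the same alone (camera adjusted p = 0.0538): the keratins KRT8 and KRT18 were 1.54-fold and 1.19-fold higher, CPS1 1.06-fold higher and the transcription factor gene FOXA1 1.53-fold lower. The rise of CPS1 was lost when libraries were scaled by totals alone. Of 6 tested cholangiocyte and progenitor markers 2 were higher and 2 lower, the same alone (camera adjusted p = 0.695), with the mucin MUC1 2.15-fold higher. Of 12 stellate cell and fibroblast markers 5 were higher and 1 lower, the same alone (camera adjusted p = 0.0120; adjusted p = 0.187 with an estimated correlation, 0.155 against matched lists), with LOX, a collagen cross-linking enzyme, 1.55-fold higher and the actin gene ACTA2 2.07-fold lower. Of the leukocyte markers 5 were tested, 1 higher and 1 lower, the same alone (camera adjusted p = 0.918). Of the endothelial markers 3 were tested and none (0) passed in edgeR, too few for a list test.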

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

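The minimum fold of 2, the protein-coding genes and the matched random lists were chosen after seeing the data. The lower expression of RNF11 and the higher expression of HINT1 kept their direction under all alternatives run, and HINT1 stayed past the threshold except in the test against a 1.5-fold change (log2 fold change 0.18), which asks for more than HINT1 shows. That test left 84 changed genes, 55 higher and 29 lower, and the minimum fold of 2 left 215, 92 higher and 123 lower, both by their construction. Scaling by totals alone gave 1335 higher and 3255 lower genes, and shifted the median log2 fold change of all tested genes from -0.00793 to -0.0722. Of its 4590 calls, 3323 were shared with the 4336. Upper-quartile factors gave 46.4% of calls higher. The other settings gave 4038 to 4399 changed genes, DESeq2 4105 with 264 adjusted p-values not given. Leaving out 1 library gave 3478 to 3978.

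With the replicate number as a block, 4399 genes changed, 4292 of them shared. The numbers do not pair the libraries: same-numbered libraries of the 2 arms had correlations of deviations from -0.0159 to -0.00586, and 0 of 6 libraries correlated best with its own number. Under the block the NF-kB list (adjusted p = 0.135) and the apoptosis list (0.0559) did not pass, and no other list past the threshold and no gene taken by the naming rule lost its call.

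Of the 141 genes taken by the naming rule, CPS1 and FTL lost the call with totals alone, and RPTOR and CYP1A1 in DESeq2. Genes that lost it when certain single libraries were left out included ABCB1, IFIT2 and CYP1A1. Of the genes that lost a call in these settings, CPS1, RPTOR, ABCB1 and CYP1A1 are also named in the Results above. The test against 1.5-fold ended the call on 113 of the 141. Of the 14 lists, 12 did not pass with an estimated correlation, while fry, which does not compare a list with other genes, passed 10 more. Without a filter the NF-kB and apoptosis lists did not pass, nor did the NF-kB list with protein-coding genes only. Without shRNF11 replicate 1, 4 more lists passed: endoplasmic reticulum chaperones (adjusted p = 0.0320), hepatocyte markers (0.0329), fatty acid oxidation (0.0451) and YAP/TEAD targets (0.0483). Hepatocyte markers also passed without shRNF11 replicate 3 (0.00927), and both they and fatty acid oxidation without shControl replicate 3 (0.0410 each). The hepatocyte list passed with the filter at 5 CPM (0.0129), endoplasmic reticulum chaperones without a filter (0.0439), and the integrated stress response (0.0488) and S-phase lists (0.0254) with totals alone. Against matched random lists, 8 lists were lost, the S-phase list passed (0.00583) and the ribosomal list changed sign (adjusted p = 0.821), as its background there is other abundant genes, which were higher as a whole. Depth limits genes with few reads: in the fifth of tested genes with the lowest expression, up to 2.74 CPM, 89 were higher and 159 lower, against 1154 and 348 in the fifth with the highest.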

Other observations

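In this part, the tests of secreted hepatocyte proteins, of scaling and of a metal response were chosen after the results were seen, as were the genes named in the next 2 paragraphs.

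All 4 tested metallothionein genes were higher in shRNF11 cells, with MT1X 2.28-fold and MT1F 2.60-fold higher beside MT1E and MT2A. All 3 tested AKR1C reductases, which act on steroids and prostaglandins, were 1.89-fold to 2.45-fold higher. Reads of such close relatives cannot be assigned to one gene with certainty. Of 15 tested genes of the circadian clock 5 were higher and 3 lower: PER2 was 1.43-fold higher and CRY1 1.21-fold beside PER1, while the repressor gene NR1D2 was 1.61-fold lower. NR4A3, a relative of NR4A2, was 1.56-fold lower. HIF1A transcripts were higher, at 1071 ± 21.9 CPM against 793.3 ± 7.29 CPM (SD, n = 3 each), and those of the membrane protein gene TM4SF1 were lower, at 416.9 ± 4.45 CPM against 746.7 ± 27.7 CPM. Of 12 tested keratins 6 were higher and 3 lower.

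PKHD1L1, which encodes a large receptor-like protein, had 58, 54 and 42 reads in the shControl libraries and 0 in each shRNF11 library, which is at least 50.2-fold lower when 3 reads over the arm are taken as the floor. LOC102724594 was called lower, but 1 library stood apart: it had 1693 reads in shControl replicate 2 and 107 to 130 in each of the other 5 libraries. Among the table's own KEGG terms, 45 of 313 passed camera upward and 1 downward with the preset correlation, led by the proteasome (33 of 42 genes higher, 0 lower), bacterial invasion of epithelial cells (38 and 1 of 67) and Parkinson disease (105 and 13 of 220), a term rich in proteasome and respiratory chain genes. With an estimated correlation 0 passed.

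The table of human genes under labels of a mouse line may be read in more than one way. If mouse reads had been counted against human genes, genes without a mouse counterpart would draw almost no reads. The 19 listed of 20 such genes were mostly primate zinc finger genes and APOBEC3 genes. They had a median of 4.37 CPM over the 6 libraries, and 13 of them had at least 1 CPM, which argues against that reading. CPM in this paragraph was taken over library totals without TMM factors. Human cells other than the labelled hepatocyte line stay open as a hypothesis: the 10 listed of 16 secreted hepatocyte proteins had a median of 0.0325 CPM, and the highest of them, FGG, 0.184 CPM. Which cells these were was not tested, and a table that belongs to other libraries than those described stays open too. The medium and the hypoxia are known only from the same labels, so under either reading they are uncertain as well.

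The rise of glucocorticoid target genes was weighed against scaling and a metal response. Its median log2 fold change stayed at 0.794 or more under totals alone and under DESeq2-style factors, so the choice among these scalings does not account for it. That choice shifts all genes nearly alike, with the median of all tested genes going from -0.00793 with TMM factors to -0.0722 with totals alone. A shift of that size could not have removed the rise. A metal response stays open: without MT2A, the metallothionein in the list, the median was 0.830, but leaving out any 1 of 10 members kept it high, so that test decides nothing, and of 2 genes tied to metal control SLC30A1 was 1.08-fold higher and MTF1 did not pass. A second list of glucocorticoid-induced genes had 5 of 11 tested members higher and 0 lower (CEBPD, MAOA, STOM, ACSL1 and LPIN1). The camera p of this list was 0.00505 at the preset correlation and 0.115 with an estimated one, so a broader rise passed only at the preset setting. NR3C1, the receptor gene, was 1.09-fold lower, and SGK1 was lower as well. A stronger response to the dexamethasone in the medium after RNF11 knockdown is a hypothesis that these libraries cannot decide. None was kept without dexamethasone per the labels, and those labels may not describe the cells counted. Handling that differed between arms, or effects of the hairpin beyond RNF11, were not tested.

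Non-coding genes were lower as a group: 158 of 1467 tested were lower and 43 higher, with a median log2 fold change of -0.200, against 1830 lower and 2305 higher of 12022 protein-coding genes. They made up 0.966% of counts in shControl and 0.877% in shRNF11, with no overlap between arms (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Low abundance may account for part of this. Protein-coding genes matched on mean expression had a median of -0.0751, which left a difference of -0.125 (bootstrap 95% interval -0.155 to -0.0938, 2000 draws over genes, which are not independent), so abundance alone falls short of the whole shift. A difference in RNA quality or in unspliced RNA between the arms was not tested.

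Of the 10 ways to divide the 6 libraries into groups of 3, the study's own gave 4336 changed genes and the highest other gave 2; 1 of 10 reached the real count. For gene lists past the camera threshold the real division gave 14 and the highest other 10, again 1 of 10. With 10 divisions no share under 0.05 can be reached. The other divisions mixed the arms unequally, so part of the arm difference remained between their groups and also widened the spread within them. Their counts of genes and lists thus do not show what libraries without an arm difference would give.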
